A study of Mus musculus with 10 samples.

How the data were processed

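The study measured 5-carboxylcytosine (5caC), an oxidised form of 5-methylcytosine, at single CG sites in genomic DNA of mouse embryonic stem cells. The 10 samples formed 5 groups of 2 technical replicates each, per the series design text. Wild-type (wt) cells and cells labelled Tdg were each grown in serum or in serum-2i, which is serum with 3 µM CHIR99021 (an inhibitor of the kinase GSK3) and 1 µM PD0325901 (an inhibitor of the kinase MEK). Tdg encodes thymine DNA glycosylase, the enzyme that excises 5caC; the labels give the gene name without the kind of alteration. The control group was DNA of serum-grown cells with all Tet genes knocked out, which lack the enzymes that make 5caC. The design text calls the culture states naive and primed.

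Per the labels' protocols, 5-hydroxymethylcytosine was blocked by glycosylation and unmodified CGs by methylation. An engineered SssI methyltransferase then removed the carboxyl group and attached an azide tag. Tagged fragments were joined to a biotin oligonucleotide, enriched on streptavidin, primed at the tagged base, amplified and sequenced on an Ion Proton. The genome build was mm10, per the submitters' processing notes. The aligner and the site caller are not given in the sources used here.

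The authors' deposited table gave a coverage value, a signal that is never negative, for each listed CG position and group. It held 1183229 entries at 922427 positions on 19 autosomes and X. Each deposited coverage value was a multiple of 0.5 and was read as the mean of a group's 2 technical replicates. The table carried no value per replicate and no strand, and it held no entry for the control group, so neither the spread between replicates nor the background could be computed and the control is not analysed here. Every group was listed only from a minimum mean coverage upward, which was 3 in the serum wt group, 4 in serum-2i wt and 6 in either Tdg group. A position missing from a group was therefore taken to have an unknown value, not a value of 0. It may have lain below that minimum or been removed by another filter, since the rule for listing is not given in the sources used here. The number of sequenced reads per library is not given in the sources used here, so the summed listed coverage stood in for depth. Whether positions are counted from 0 or from 1 could not be settled, which matters by 1 base; they are printed as the table gives them.

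Gene names and spans came from an NCBI RefSeq table of the assembly GRCm38.p6, the same assembly as mm10, with 49554 genes on these chromosomes, 21631 of them protein-coding. The table gave no strand and no transcription start, so "near a gene end" means within 1 kb of either end of a protein-coding span. No genome sequence was used, so densities are per length and not per CG. For each gene, for each 100 kb window and for each site, the listed sites were counted and their coverage was summed. A gene's span was taken without flanks, and a site inside overlapping spans counted for each of them. Genes and windows were kept where the summed coverage averaged at least 20 over the 4 listed groups, which left 19380 genes (13211 protein-coding) and 16763 windows.

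Groups were compared by the log2 ratio of a feature's share of the group's summed coverage. Each ratio carries an exact conditional Clopper-Pearson 95% interval from the coverage summed over the 2 replicates. These intervals cover counting error only: PCR reads without molecular identifiers are not independent molecules, a read can cover several CGs, and no spread between cultures enters. Count models with replicates had been planned for genes, windows and sites, and set tests on those models for gene lists. With 1 value per group they were not run, no p-value was computed, and the fallback written with that plan was used. A feature was called higher or lower where its share differed by at least 2-fold and its interval excluded no difference, and otherwise between; this size rule was set after the table was seen. Where a group listed no site in a feature, no ratio was computed. The interaction of medium and genotype was not tested. Counts of called genes and windows are given for the comparison of media in Tdg cells and for Tdg against wt in serum-2i, and once for the media in wt cells as a base share. The serum wt group had only 8685 listed sites, so a gene needed at least 1 of them to enter a ratio, and its comparisons are given as site ratios, sums over lists and selected genes.

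Before the data were examined, 14 gene lists with 290 symbols were fixed. They cover naive, general and primed pluripotency, the DNA methylation machinery, germline genes silenced by methylation in somatic cells, and imprinted genes. They also cover lineage regulators with bivalent promoters, neural, fibroblast and extraembryonic markers, WNT and ERK pathway genes, housekeeping genes and silent tissue-specific genes. All 290 symbols were found, 2 of them by an older symbol. A list's median log2 ratio was placed among 10000 random lists of the same size, matched on summed coverage. Lists were also placed among lists matched on span length, and on span length with coverage. Percentiles describe these libraries and are not tests between conditions. For comparisons with the serum wt group, where few members had a ratio, the coverage was summed over a list's kept members. Sums are also given for Tdg over wt in serum-2i, and percentiles of sums are from lists matched on span length with coverage.

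Named genes followed a rule fixed before the data were examined: per comparison the 10 highest and 10 lowest log2 ratios whose intervals excluded no difference, leaving out predicted symbols, up to 4 members of each list by size of the ratio, and Tet1, Tet2, Tet3 and Tdg. Only a part of the names the rule gives is printed for the serum wt comparisons. Windows and sites followed the same ranks with 5 each way. Gene families, the genes with most sites and the members of the lists named beyond 4 were chosen after the values were seen. The values of 3 single genes of the lists are not reported here.

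The alternatives tried were median-ratio and trimmed-mean scaling, no coverage filter, the number of sites in place of coverage, 1 Mb windows, a mean site coverage of at least 20, spans with 2 kb added on each side, positions within 1 kb of a span end, common coverage minimums of 6 and 10, unscaled coverage, other matching of the random lists, and lists without their shared genes. All steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

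The ratio step was tested on simulated coverage drawn for the real genes, with 200 genes altered. Simulated coverage varied by counting error alone, which is what the intervals assume. A share near 95% of intervals holding the true value was therefore built in. Neither the coverage minimums for listing nor the dependence between PCR reads was simulated. The test checks the calculation only, and its rates of wrong and missed calls do not describe the calls made on the deposited values. For serum-2i over serum in Tdg cells, over 18052 genes, the interval held the true value for 95.6%, no unaltered gene was called, and 50 of 50 genes altered 3-fold and 23 of 50 altered 2-fold were called. For Tdg over wt in serum-2i, over 15054 genes, the figures were 95.9%, 52 unaltered genes called, 49 of 50 at 3-fold and 25 of 50 at 2-fold. For serum-2i over serum in wt cells, over 3452 genes, they were 97.3%, 59, 38 of 50 and 16 of 50. For Tdg over wt in serum, over 3867 genes, they were 96.8%, 68, 39 of 50 and 23 of 50. In the first of these comparisons a simulated list of 30 genes shifted by 1 log2 unit fell at percentile 2.15, and 10 of 200 unshifted lists fell outside the central 95%.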

Results

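Base-resolution 5caC at CG sites was measured in mouse embryonic stem cells of 4 groups, wt and Tdg cells in serum and in serum-2i, with 2 technical replicates each, and values were given as the mean coverage of each group. The serum wt group had 8685 listed sites with a median coverage of 4.5 and a summed coverage of 43172. The serum-2i wt group had 110753 sites with a median of 7.5 and a sum of 890158.5. In Tdg cells, 374488 sites were listed in serum (median 14.5, sum 7486660) and 689303 in serum-2i (median 13.5, sum 12348368). There was no value per replicate, so no difference below could be set against the spread between replicates.

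Tdg cells had 43.1 times as many listed sites as wt cells in serum and 6.22 times as many in serum-2i. Serum-2i had 12.8 times as many as serum in wt cells and 1.84 times as many in Tdg cells. These ratios depend on the coverage minimum, which was lower in the wt groups: from a common minimum of 6 upward, the wt groups had 2006 and 82193 sites, and the ratios in the same order were 187, 8.39, 41.0 and 1.84. Read numbers per library were unknown, so the ratios describe listed sites and not amounts of 5caC.

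A 5caC site was listed in 16303 of 21631 protein-coding genes (75.4%) in serum-2i Tdg cells and in 14390 (66.5%) in serum Tdg cells. Among wt cells, 12144 genes (56.1%) had a site in serum-2i and 3351 (15.5%) in serum. Gse1, a coiled-coil protein of a histone demethylase complex, held the most sites of any protein-coding gene in either Tdg group, 655 in serum and 653 in serum-2i, against 36 and 146 in wt cells. Next in serum Tdg cells came Zfhx3 (383 sites), a zinc-finger homeobox factor, Nfix (346), a nuclear factor I family member, and Casz1 (300), a zinc-finger factor of heart and eye development. In serum-2i Tdg cells they were Msi2, an RNA-binding protein, and Zfhx3 with 643 each, followed by Slc39a11 (580), a zinc transporter, and Tenm3 (568), a neuronal adhesion protein. These genes were chosen after their values were seen. They were ranked by number of sites, and their spans are long, from 96.5 kb (Nfix) to 1297 kb (Tenm3), against a protein-coding median of 17.3 kb. By sites per kb, among genes with at least 10 sites and without predicted symbols, other genes led. They were Prm1 in serum Tdg cells (12 sites in 0.492 kb) and Olfr279 in serum-2i Tdg cells (18 sites in 0.933 kb).

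The fixed gene lists differed in how many sites they held relative to random protein-coding genes of the same span. Lineage regulators with bivalent promoters held 1944 sites in serum Tdg cells, 7.59 times the random median (percentile 100), and 668 sites in serum-2i Tdg cells, 1.94 times (percentile 99.7). In wt cells the same list stood at 4.50 times in serum (27 sites) and 1.10 times in serum-2i (68 sites, percentile 62.5). The germline list holds genes silenced by DNA methylation in somatic cells, such as the meiotic genes Sycp1 and Sycp3. It held 0.352 times the random median in serum Tdg cells, 0.330 times in serum-2i Tdg cells (percentile 0) and 0.337 times in serum-2i wt cells. Random genes were not matched on chromosome, so any list members on X, where listed sites were few, would lower these figures. Housekeeping genes held 0.421 times in serum Tdg cells (percentile 1.71) but 0.810 times in serum-2i Tdg cells (percentile 22.3), and 1.67 and 0.667 times in serum and serum-2i wt cells (5 and 12 sites); Gapdh, Eef1a1 and Hspa8 had no listed site in either Tdg group. Other lists also stood above the central 95% of random lists in Tdg cells. In serum they were extraembryonic markers (2.91 times), primed genes (2.88), ERK pathway genes (2.54), WNT pathway genes (2.25), DNA methylation genes (2.09) and naive genes (2.05), and in serum-2i ERK pathway (2.64), naive (2.25), WNT pathway (2.06) and DNA methylation genes (1.71).

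**Figure D1:**
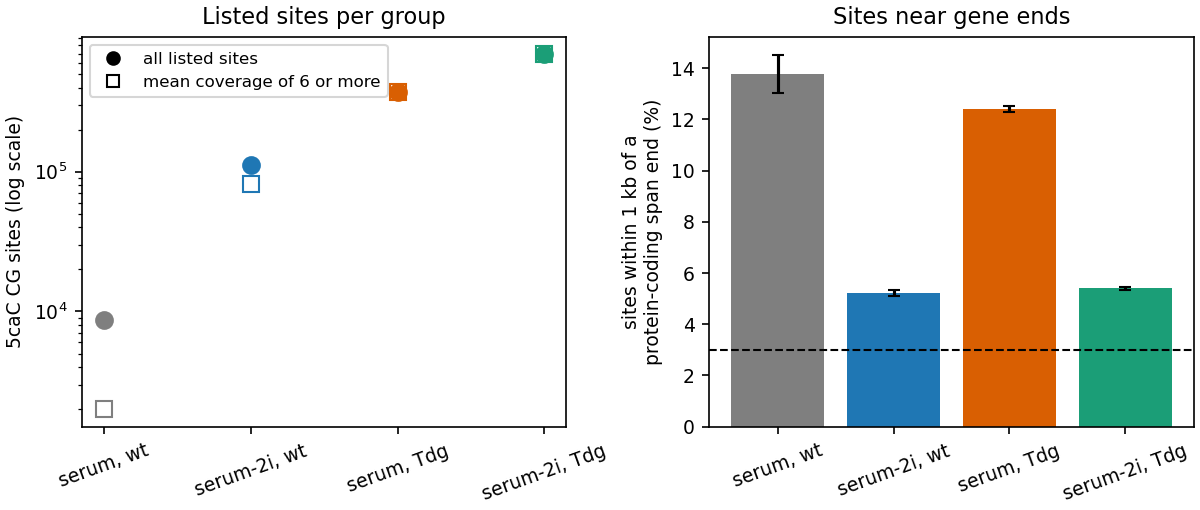
Left, listed 5caC CG sites per group on a log axis, for all sites (filled circles) and for sites with a mean coverage of 6 or more (open squares); the groups run from 8685 to 689303 sites. Right, the percentage of listed sites within 1 kb of an end of a protein-coding span, with exact 95% intervals of counting error; the dashed line is the 2.98% of length that lies there.

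Sites lay near gene ends more often in serum than in serum-2i. Within 1 kb of a protein-coding span end, which covers 2.98% of the length, lay 13.8% of sites in serum wt cells (exact 95% interval 13.0 to 14.5) and 12.4% in serum Tdg cells (12.3 to 12.5). The serum-2i groups had 5.22% (5.09 to 5.35) in wt and 5.41% (5.36 to 5.46) in Tdg cells. Protein-coding spans as a whole, 39.1% of the length, held similar shares in all 4 groups: 58.6% and 59.2% in serum wt and Tdg cells, 61.2% and 56.5% in serum-2i wt and Tdg cells. Serum Tdg cells also had more tight runs of at least 10 sites with gaps of at most 100 bp, 1110 against 429 in serum-2i Tdg cells, and neither wt group had any. Drawn down to 8685 sites per group, a site had another within 1 kb for 14.2% of sites in serum wt, 10.9% in serum Tdg, 3.90% in serum-2i wt and 4.58% in serum-2i Tdg cells.

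Chromosome 11 had the highest density of listed sites per Mb in every group, from 1.51 times the autosomal mean in serum-2i Tdg cells to 2.37 times in serum wt cells. Chromosome X had the lowest, at 0.121 times the autosomal mean in serum-2i Tdg, 0.108 in serum Tdg, 0.0572 in serum-2i wt and 0.0667 in serum wt cells. Serum wt had only 40 sites on X. Bcor on X, a corepressor of a Polycomb complex, was an exception chosen after its values were seen: it held 241 sites in serum Tdg cells and 94 in serum-2i Tdg cells, but 4 and 5 in the wt groups.

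**Figure D2:**
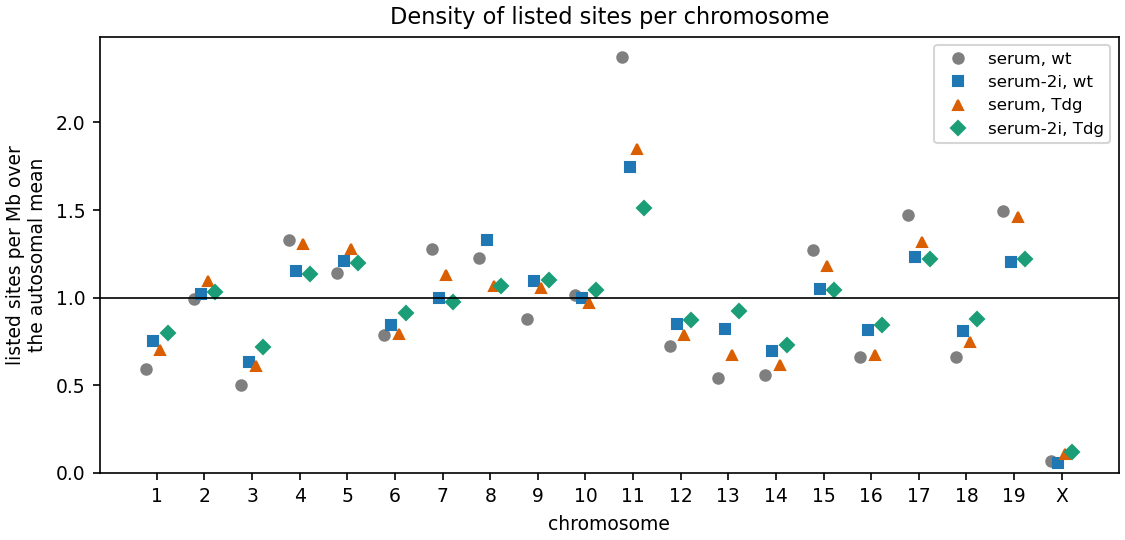
Listed sites per Mb on each chromosome over the autosomal mean, for the 4 groups. Chromosome 11 lies highest and chromosome X lowest in each group.

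Many sites of a wt group were also listed in the Tdg group of the same medium. In serum this held for 4730 of the wt sites (54.5%, exact 95% interval 53.4 to 55.5), and in serum-2i for 54406 (49.1%, 48.8 to 49.4). Among positions listed in at least 1 of the remaining groups, the share also listed in the Tdg group was 2.84 times and 1.61 times that over all such positions. Between media, 197737 sites of serum Tdg cells (52.8%) were listed in serum-2i Tdg cells, and 993 sites of serum wt cells (11.4%) in serum-2i wt cells, with excesses of 1.67 and 2.35 times by the same measure. All 4 groups shared 610 sites, and 681712 of the positions were listed in 1 group alone.

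The comparison of serum-2i with serum in Tdg cells asks how the culture state alters where listed 5caC lies in these cells. Regulators of cell lineage had a smaller share of 5caC coverage in serum-2i than in serum. Barx1, a homeobox factor of tooth and stomach, had 1 listed site in serum-2i and 44 in serum (log2 ratio -7.72, interval -8.59 to -6.97), the lowest ratio of all named genes in this comparison. Tbx3, a T-box factor of limb and heart that also belongs to the naive pluripotency network, had 2 against 36 (-6.17), Hoxb9 1 against 14 (-6.05), and Cbx8, a subunit of Polycomb repressive complex 1, 2 against 33 (-5.77). The highest ratios were those of genes with a single listed site in serum, such as Tmc1, a channel of inner-ear hair cells, with 47 sites against 1 (6.17, interval 5.45 to 7.01), and Ect2, a regulator of cytokinesis, with 39 against 1 (5.74).

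Of the 37 kept genes of the bivalent lineage regulator list, 33 were lower, 1 was between, 3 were listed in serum alone and none was higher. The list held 668 sites in serum-2i and 1934 in serum although the serum-2i group had more sites in all. Hoxa9 had 4 sites against 37 (-4.55), the muscle and craniofacial factor Msx1 1 against 15 (-4.46, with 87.5% of its sites in another gene's span), the heart factor Nkx2-5 5 against 35 (-4.23) and the organizer gene Gsc 3 against 16 (-4.14). The endoderm factor Gata4 had 70 against 193 (-2.65) and the eye and brain factor Pax6 31 against 101 (-2.76). The endoderm factor Foxa2 had 13 sites in serum and none listed in serum-2i. Neurog1 was the member between (2 against 3, -0.81). The list's median log2 ratio was -2.90, at percentile 0 of the random lists matched on coverage, whose central 95% ran from -0.58 to 0.64, and also of those matched on span length as well, and its summed coverage had a log2 ratio of -2.62 (interval -2.64 to -2.60).

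**Figure D3:**
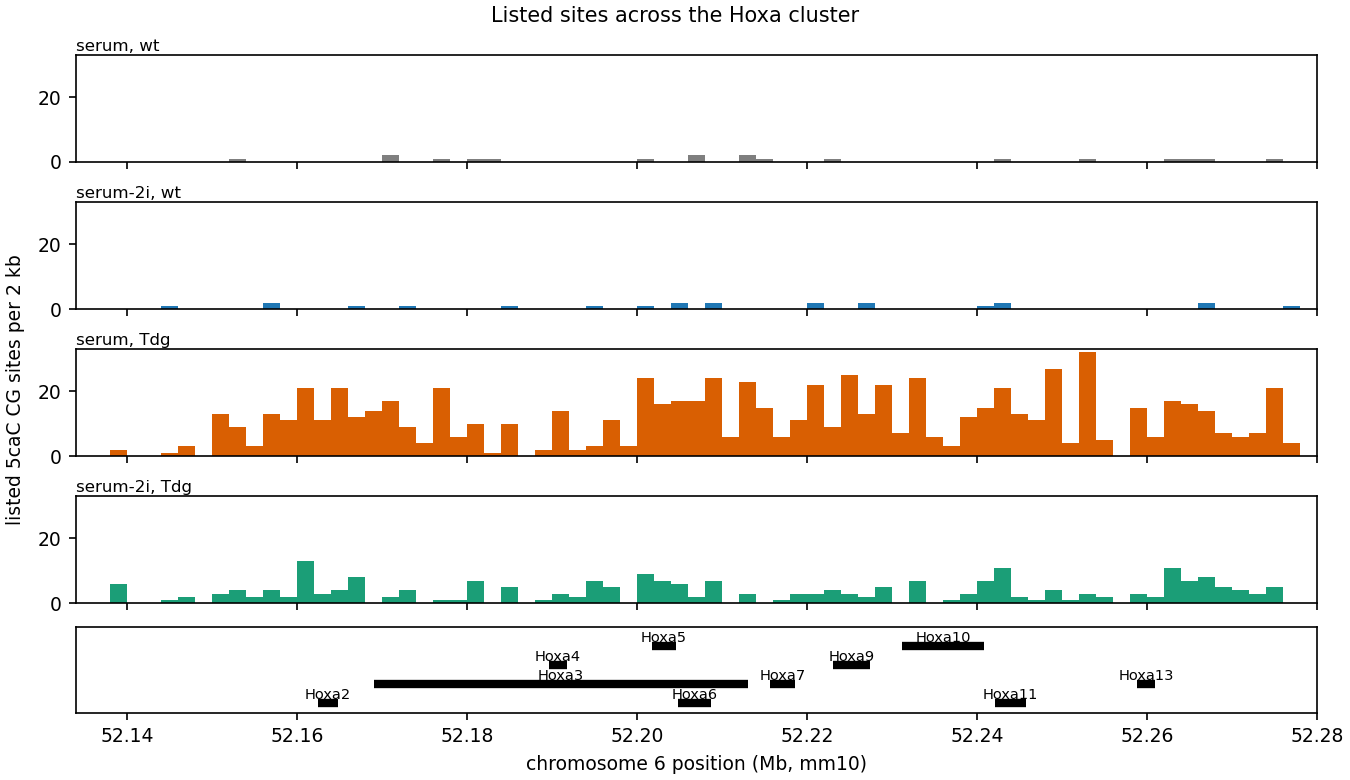
Listed 5caC sites per 2 kb across the Hoxa cluster on chromosome 6 in the 4 groups, with spans of genes below. Serum Tdg cells had 661 sites in the cluster, serum-2i Tdg cells 172, and the wt groups 14 and 18.

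Every Hox cluster followed the same direction in Tdg cells. Hoxa (chromosome 6) had 661 sites in serum and 172 in serum-2i, Hoxb (chromosome 11) 803 and 251, Hoxc (chromosome 15) 609 and 190, and Hoxd (chromosome 2) 548 and 111, which is 3.20 to 4.94 times as many sites in serum. Mean coverage per site was also higher in serum, for example 25.1 against 16.2 in Hoxa. Families were chosen after the values were seen. All 36 Hox genes listed in both media were lower, as were 8 of 9 Tbx genes, all 8 Lhx genes, all 6 Gata genes and 14 of 19 Wnt genes, and no member of these families was higher. The Hox genes lie in the clusters above, and some of their spans overlap, so they are not independent. Zinc-finger genes named Zfp went the other way more often, with 69 higher and 36 lower of 191 and 4904 sites against 2519. The axonemal dynein heavy chains (Dnah) had 8 higher and 1 lower of 14, and classical and related cadherins (Cdh) 9 higher and 3 lower of 19. These directions of the family medians held under the other scalings, which moved the median of all genes by 0.10. Families were not matched on span length. Of all 18052 genes listed in both media, 5344 were higher and 4638 lower, and all listed sites were 1.84 times as many in serum-2i. Among protein-coding genes, 56.4% of those under 10 kb were lower and 51.7% of those over 100 kb higher.

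**Figure D4:**
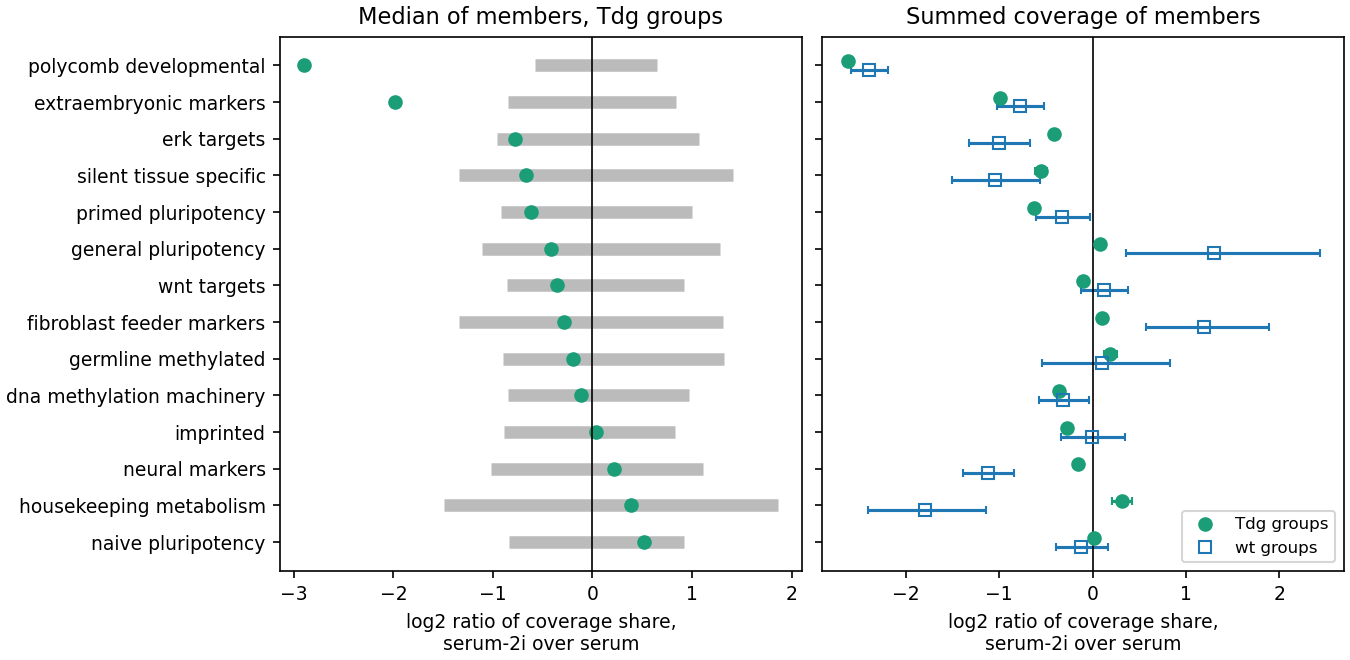
Left, the median log2 ratio of coverage share, serum-2i over serum in Tdg cells, for each gene list (points) with the central 95% of 10000 random lists matched on coverage (grey bars). Right, the log2 ratio of summed coverage with exact 95% intervals of counting error in Tdg cells (filled) and wt cells (open); the bivalent lineage regulators (polycomb developmental) lie lowest in either, at -2.62 and -2.39.

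Extraembryonic markers had 11 members lower, 3 higher and 4 between, with a median of -1.99 (percentile 0). The trophoblast factor Hand1 had 5 sites against 46 (-4.43), the endoderm factor Sox17 2 against 14 (-3.80) and the keratin Krt8 6 against 27 (-3.74), while Elf5, Dab2 and Lamb1 were higher (1.95, 1.53 and 1.38). Without the 5 genes that this list shares with the bivalent lineage regulators, the median of the other 13 was -0.10 (percentile 44.1).

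The pluripotency lists were mixed. Of the naive genes, 7 were higher, 6 lower, 6 between and Socs3 was listed in serum alone (6 sites), with a median of 0.52 (percentile 86.8, or 96.5 with span length matched too); by number of sites the median was -0.27 (percentile 30.2). Dppa4 (12 sites against 1, 3.54), Dppa2 (17 against 2, 2.99), the cytokine receptor Il6st (2.54), Zfp42 (2.37), Tfcp2l1 (1.93), Nanog (3 against 2, 1.65) and Stat3 (1.09) were higher. The call for Nanog rested on coverage at few sites: in number of sites it fell short of the 1.84-fold ratio of all listed sites. Tbx3, Klf4 (18 against 37, -2.71), Tcl1, Gbx2, Dppa3 and Klf5 were lower, and Esrrb, an orphan nuclear receptor with 216 sites against 144, was between (-0.09). Fgf4 had no listed site in either Tdg group, and neither had Sox2. General pluripotency genes had 2 higher, 5 lower and 4 between (median -0.42), among them Rif1 (13 against 1, 3.09) and the NODAL antagonists Lefty2 (1 against 6, -3.64) and Lefty1 (6 against 14, -2.33, most of its sites in another gene's span). Pou5f1, which encodes OCT4, had 6 against 8 and was also lower. Primed genes had 1 higher, 4 lower and 10 between (median -0.62, percentile 8.33, or 10.1 with span length): Zic2 had 2 against 12 (-4.19), the growth factor Fgf5 9 against 12 (-2.11) and the adhesion gene Cdh2 43 against 6 (1.88).

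Among the enzymes of DNA methylation and demethylation, 6 were higher, 4 lower and 7 between (median -0.12, percentile 35.0, or 42.4 with span length). The dioxygenase gene Tet1 had 115 sites against 28 (1.20, interval 1.10 to 1.30; 24.1% of its sites lie in another gene's span), Tet2 49 against 32 (-0.12) and Tet3 65 against 84 (-1.40). Tdg itself had 8 against 3 (1.57), Uhrf1, the cofactor of maintenance methylation, 44 against 13 (1.27), Dnmt1 81 against 44 (0.28), Dnmt3a 122 against 129 (-0.94) and the damage-response gene Gadd45b 1 against 6 (-4.34).

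Germline genes had 6 higher, 3 lower and 8 between (median -0.19). The median stood at percentile 21.7 of lists matched on coverage and at 1.12 of those matched on span length too, whose central 95% ran from -0.06 to 1.84. The members ranged up and down, with Stk31 (12 against 2, 2.57) and Sycp2 (2 against 6, -2.23) at the extremes. Of the imprinted genes, 3 were higher, 6 lower and 9 between, and 2 were listed in serum-2i alone, namely Mirg (9 sites) and Peg10 (11 sites); the median was 0.03, which falls below 0 under median-ratio scaling. The non-canonical NOTCH ligand Dlk1 had 3 against 24 (-3.88) and the growth factor gene Igf2 17 against 47 (-3.31; 40.8% of its sites overlap another gene), and Dio3, in the same imprinted domain as Dlk1, had 1 against 17 (-6.18). Meg3 (32 against 16, 0.05) and Igf2r (30 against 21, 0.01) were between. Kcnq1ot1 (3.62) and Snrpn (3.27) were higher, but all of their sites lie in other genes' spans.

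Of the pathways that the 2 inhibitors act on, WNT genes had 2 higher (Ctnnb1, 15 against 3, 2.56; Lgr5, 66 against 13, 2.07), 5 lower (Dkk1 lowest, 1 against 6, -3.82) and 10 between, with a median of -0.36. ERK pathway genes had 1 higher, 6 lower and 7 between (median -0.77, percentile 5.54, or 48.9 with span length matched too), and the immediate early genes Egr1 (4 against 19, -3.65), Fosl1 (10 against 27, -2.91), Fos (4 against 9, -2.69) and Myc (7 against 11, -1.89) were lower. Neural genes had 6 higher, 3 lower and 4 between (median 0.21). The glutamate receptor gene Grin2b (92 against 15, 2.01) and the adhesion gene Ncam1 (92 against 30, 1.21) were higher, while Gad1 (18 against 52, -3.06) and Gfap (5 against 15, -2.82) were lower. Fibroblast markers had 1 higher (Fn1, 109 against 18, 2.13), 2 lower (Thy1, -1.74, and Col1a1, -1.33) and 3 between (median -0.29). Housekeeping genes had 2 higher (Pgk1, 1.77, and Ldha, 1.56), 1 lower (Aldoa, -2.47) and 4 between, among them Pkm (0.39), with a median of 0.39. Silent tissue-specific genes had 1 higher (Cd8a, 1.32), 3 lower (Myh7, -1.51, all of its sites in another gene's span, Actn3, -1.29, and Myh6, -1.14) and 5 between (median -0.67). For several of these genes the sign turned when only positions near the span ends were taken: Grin2b, Ctnnb1, Ldha, Pkm, Cd8a, Myh7 and Actn3. List medians moved there too. WNT genes stood at -2.25 (percentile 1.13) and silent tissue-specific genes at 1.49 (4 members, percentile 97.6), outside the central 95% of random lists. The bivalent lineage regulators (-3.15, percentile 0) and extraembryonic markers (-3.04, percentile 0.18) lay below it as well. Naive (-1.34), neural (-1.81), imprinted (-1.93) and housekeeping genes (-0.90) turned negative within it. Random lists moved down there too, for naive genes to -2.13 to 0.20, against -0.84 to 0.92 over whole spans.

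The ratio increased with the length of the gene. Among protein-coding genes listed in both media, spans under 10 kb had a median log2 ratio of -1.31 (2267 genes, 10.5% higher and 56.4% lower). Spans of 10 to 30 kb had -0.26, spans of 30 to 100 kb 0.38, and spans over 100 kb 1.05 (2175 genes, 51.7% higher and 3.26% lower). Spearman's rho across 12576 genes, which are not independent replicates, was 0.454. Genes listed in 1 medium alone had no ratio, and whether leaving them out shaped the trend was not tested. Long genes chosen after their values were seen illustrate it: the tumour suppressor Wwox had 92 sites in serum and 534 in serum-2i, the cadherin Cdh13 45 and 450, and the scaffold protein Magi1 57 and 443. At the other end, Tlx1, a homeobox factor of spleen development, had 114 and 26, and Dlx5, a craniofacial homeobox factor, 60 and 12. The other genes of highest ratio were Kcnip4 (56 against 1, 6.01), Bhmt (23 against 1, 5.68), the receptor kinase gene Mertk (27 against 1, 5.58), Dhcr7 of cholesterol synthesis (17 against 1, 5.49), the epithelial factor Trp63 (31 against 1, 5.41), Grm7 (28 against 1, 5.37), Ap1s3 (20 against 1, 5.35) and the telomere protein Pot1a (27 against 1, 5.29). Those of lowest ratio included the purine-degradation gene Urad (1 against 32, -6.76), Klf14 (1 against 15, -5.78), Gp1bb (1 against 18, -6.07), Ecel1 (2 against 30, -5.91) and Ly6g6e (1 against 11, -5.73); of the sites of the last 3, 60.0%, 93.9% and 100% lie in another gene's span.

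**Figure D5:**
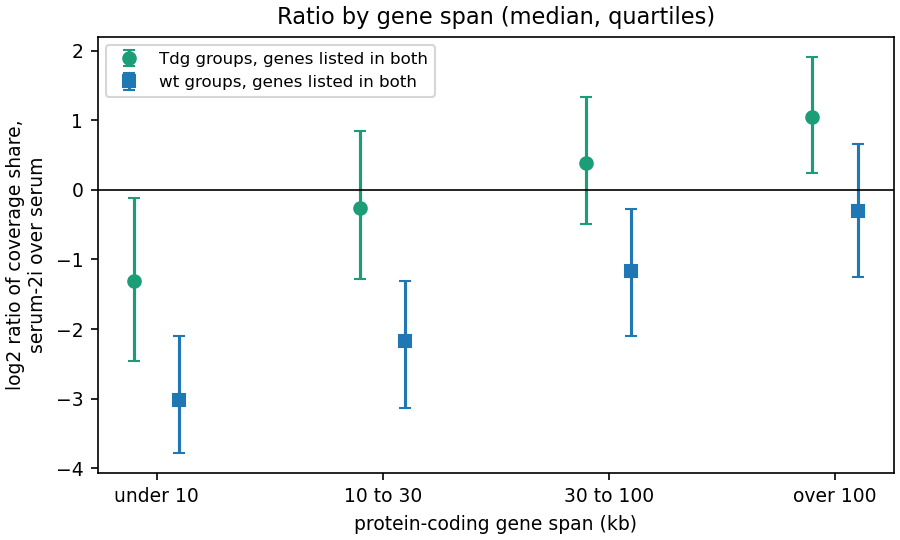
Median (points) and quartiles (bars) of the log2 ratio of coverage share, serum-2i over serum, by span length of protein-coding genes listed in both groups, for Tdg cells (circles) and wt cells (squares). In Tdg cells the median runs from -1.31 under 10 kb to 1.05 over 100 kb, and in wt cells from -3.02 to -0.31. A gene entered the wt medians only with at least 1 serum wt site, which limits how high the ratio of a short gene can be. Of the 315 such genes under 10 kb, 292 were lower and 0 higher, so the wt trend may follow in part from this condition. The Tdg medians likewise needed a serum Tdg site: of all kept genes, 1215 were listed in serum-2i alone and 113 in serum alone.

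Over all 18052 genes listed in both media in Tdg cells, 5344 were higher in serum-2i, 4638 lower and the median was 0.10; 1215 further genes were listed in serum-2i alone and 113 in serum alone. By number of sites instead of coverage, 1724 were higher and 2814 lower, and within 1 kb of span ends 1628 were higher and 5258 lower. Of the 14887 windows of 100 kb listed in both, 6489 were higher and 1456 lower (median 0.74), or 4197 and 3609 with median-ratio scaling and 4123 and 3700 with trimmed-mean scaling. The highest windows included chromosome 18 from 44400001 (Dcp2 and Mcc, 52 sites against 1, 6.45), chromosome 2 from 76800001 within the muscle gene Ttn (85 against 1, 6.30) and chromosome 9 from 47600001 within the adhesion gene Cadm1 (70 against 1, 6.05). The lowest included the windows at Nr2f1, a nuclear receptor of brain patterning (chromosome 13 from 78100001, 11 against 73, -4.48), and at the homeobox gene Irx1 (chromosome 13 from 71900001, 5 against 46, -4.46). At the 197737 sites listed in both media, median coverage was 18.5 in serum-2i and 17.5 in serum, and the median of the ratios per site was 1.04-fold. Scaled by summed coverage, 13728 of these sites were higher and 75659 lower, while unscaled coverage gave 39918 and 35500, and median-ratio scaling 36757 and 37544, a shift of the median by -0.67. The highest site lay in the planar polarity gene Celsr1 (chromosome 15, 86009891, coverage 199 against 7.5) and the lowest in Cdca4 (chromosome 12, 112820815, 6 against 133.5).

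The comparison of media in wt cells asks the same question of the other genotype. The bivalent lineage regulators again had a lower share in serum-2i: summed over the list, 68 sites in serum-2i and 27 in serum gave a log2 ratio of -2.39 (interval -2.58 to -2.19, percentile 0.15). The 10 members listed in both media were lower, a condition under which 2131 of 3452 genes were lower and 156 higher (835 and 925 with median-ratio scaling). They included Lhx5 (1 against 2 sites, -4.87), Gata2 (4 against 3, -3.18), the heart and limb factor Tbx5 (10 against 5, -3.17) and Gata6 (2 against 1, -2.88). Cbx8 (2 against 5, -5.93), the glutamate transporter Slc17a7 (1 against 4, -5.81) and the amino acid transporter subunit Slc3a2 (1 against 2, -6.28) were among the lowest genes, and Igf2 had 3 against 4 (-4.33). Highest were Btbd9 (54 against 1, 2.77), Pakap (48 against 1, 2.73), Dnah8 (59 against 1, 2.72), the lymphoid repressor Bach2 (45 against 1, 2.69) and the actin-binding Ablim1 (50 against 1, 2.66). Tet1 had 19 sites in serum-2i and none listed in serum, Tet2 8 against 2 (-2.39), Tet3 15 against 2 (-0.91), and Tdg none in either.

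Among the other lists in wt cells, summed log2 ratios were -0.78 for extraembryonic markers (104 against 12 sites), -1.12 for neural (77 against 11, percentile 1.25), -1.01 for ERK pathway (51 against 8), -1.05 for silent tissue-specific (22 against 4), -1.80 for housekeeping (11 against 3), -0.33 for primed (105 against 10), -0.32 for DNA methylation (124 against 11), -0.12 for naive (127 against 11) and -0.01 for imprinted genes (93 against 7). They were 0.10 for germline (28 against 2), 0.13 for WNT pathway (180 against 13), 1.19 for fibroblast (60 against 3) and 1.30 for general pluripotency genes (29 against 1). The intervals of naive, imprinted, germline and WNT pathway genes included 0. Mean coverage per listed site was 8.04 in serum-2i and 4.97 in serum. Median-ratio scaling would raise every sum by 1.64 and leave only the lineage regulators and the housekeeping genes below 0, but that factor comes from the genes listed in both media alone, while the sums include members with no serum wt site. Against matched random sums, the lineage regulators and neural genes lay below the central 95%, and housekeeping genes (percentile 9.39) did not. Scaled by total coverage, the housekeeping list, with 0.31 in Tdg cells (72 against 38 sites), was the only list whose interval lay on opposite sides of 0 in wt and Tdg cells; the difference was not tested. With the wt sums raised by 1.64, other lists would differ in sign too, such as neural (-0.16 in Tdg cells) and ERK pathway genes (-0.41). At the 993 sites listed in both media, median coverage was 9 in serum-2i and 4.5 in serum, and the median of the ratios per site was 1.86-fold. Across 2892 protein-coding genes with a site in all 4 groups, the ratio of media in wt cells had a Spearman's rho of 0.399 with that in Tdg cells (Pearson's r 0.388), and 0.674 (0.692) across the 98 genes with at least 5 sites in each group. Both ratios rose with span length, and the correlations were not adjusted for it.

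Tdg against wt cells in serum asks where listed 5caC differed between the genotypes, whose kind of Tdg alteration is not given. Of the kept genes, 18085 had more listed sites in Tdg cells and 49 had fewer. Tdg cells had 43.1 times as many listed sites in all, and the Tdg groups gave most of the coverage by which genes were kept. The split follows largely from both and is not a result about single genes. Cuedc1 had 187 sites against 1 (log2 ratio of share 2.96, interval 1.91 to 4.27), the Polycomb subunit gene Cbx7 91 against 1 (2.45), Lhx2, a homeobox factor of eye and forebrain, 139 against 1 (2.42), the bicarbonate transporter Slc4a8 129 against 1 (2.25) and the homeobox gene Cux2 180 against 1 (2.24). Pax6 had 101 against 1 (1.10), Gata4 193 against 3 (0.61) and Dnmt3a 129 against 1 (1.45), while Igf2 had 47 against 4 (-1.69) and Tet2 32 against 2 (-2.35). The lowest shares were those of genes with no more sites than in wt cells: Efcab2 with 1 against 3 (-7.67), the zinc-finger gene Zfp976 with 1 against 2 (-7.48) and Jrk with 2 against 2 (-7.19). Tet1 had 28 sites and Tdg 3 in Tdg cells, and neither had any listed in wt cells.

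The summed share in serum was higher in Tdg cells for general pluripotency genes (159 against 1 site, 2.09), the bivalent lineage regulators (1934 against 27, 0.91, interval 0.74 to 1.09, percentile 91.9), fibroblast markers (164 against 3, 0.89) and primed genes (582 against 10, 0.32). It was lower for housekeeping genes (38 against 3, -1.97), silent tissue-specific (104 against 4, -0.92) and neural genes (391 against 11, -0.63). The intervals included 0 for imprinted (385 against 7, 0.19), WNT pathway (610 against 13, 0.11), extraembryonic (649 against 12, 0.03), germline (96 against 2, -0.41), DNA methylation (456 against 11, -0.24), ERK pathway (316 against 8, -0.22) and naive genes (443 against 11, -0.21). Mean coverage per listed site was 19.99 in Tdg and 4.97 in wt cells. Median-ratio scaling would raise every sum by 1.36 and leave only the housekeeping genes below 0, but that factor comes from the 3867 genes listed in both genotypes alone. No list lay outside the central 95% of matched random sums; the lowest were neural (percentile 6.97), silent tissue-specific (12.1) and naive genes (16.6), after housekeeping genes. Of the windows of highest ratio, chromosome 5 from 28100001 contains the homeobox gene En2 (214 sites against 1, 2.95) and chromosome 19 from 25600001 the genes Dmrt1, Dmrt3 and Dmrt2 (145 against 1, 2.82). At the 4730 sites listed in both genotypes, median coverage was 21 in Tdg and 4.5 in wt cells, and the median of the ratios per site was 4.63-fold.

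Tdg against wt cells in serum-2i asks the same in the other culture state. Among members of the lists, the highest ratios were those of the glycolysis gene Pkm (27 sites against 1, 2.54), the threonine dehydrogenase gene Tdh (22 against 1, 2.49; 65.1% of its sites in another gene's span), the ERK feedback inhibitors Spry4 (39 against 1, 2.41) and Spry1 (16 against 1, 2.22) and the mesoderm and trophoblast factor Eomes (17 against 1, 2.10). The de novo methyltransferase gene Dnmt3b had 13 against 9 and was lower, the cell-cycle gene Ccnd1 8 against 3 (-1.79) and Fos 4 against 2 (-1.76). The highest ratios of all were those of the myosin gene Myo1f (41 against 1, 3.57, interval 2.59 to 4.79), Trappc13 (33 against 1, 3.55), the neuronal adhesion gene Cntnap4 (48 against 1, 3.35), Nectin4 (38 against 1, 3.26) and the neurotrophin receptor Ngfr (48 against 1, 3.20). The lowest were those of the ubiquitin ligase gene Rnf166 (1 against 5, -5.54), the Polycomb-associated Phf1 (2 against 4, -4.79), Nudt14 (2 against 4, -4.75) and Cdk5r1 (3 against 4, -4.40). Tet1 had 115 against 19 (-0.12), Tet2 49 against 8 (-0.08) and Tet3 65 against 15 (-0.56), and Tdg had 8 sites against none listed.

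By summed share, general pluripotency genes stood highest in serum-2i (329 against 29 sites, 0.87, percentile 99.1), but their median was 0.26 (percentile 86.0), with Jarid2, a Polycomb complex 2 subunit, at 144 against 11 (1.07) and Lefty2 at 1 against 1 (-2.67). The bivalent lineage regulators followed (668 against 68, 0.68, interval 0.59 to 0.77, percentile 99.9), with a median of 0.31 (percentile 93.8) and 3 higher, 3 lower, 11 between and 17 listed in Tdg cells alone. Gsc (3 against 1, -1.66) and Neurog1 (2 against 1, -1.79) were among the lower members. ERK pathway (454 against 51, 0.38), neural (653 against 77, 0.33), housekeeping (72 against 11, 0.14) and primed genes (703 against 105, 0.02) were also above 0, the last 2 with intervals that included it. Silent tissue-specific (131 against 22, -0.42), germline (160 against 28, -0.32), DNA methylation (628 against 124, -0.29), fibroblast (318 against 60, -0.20), extraembryonic (616 against 104, -0.18), WNT pathway (1083 against 180, -0.12), naive (776 against 127, -0.08) and imprinted genes (583 against 93, -0.07, interval including 0) were below 0. By median, the measure set for this comparison, no list lay outside the central 95% of random lists matched on coverage; the lowest percentile was that of extraembryonic genes (median -0.49, percentile 2.70). None lay outside with span length and coverage matched either. Matched on span length alone, germline genes (median -0.92, percentile 1.24) and the bivalent lineage regulators (percentile 97.8) lay outside. By number of sites the lineage regulators stood at percentile 99.3. The median ratio of the genes listed in both genotypes was -0.19, and with median-ratio scaling the summed shares of extraembryonic, WNT pathway, naive and imprinted genes were above 0. The medians of extraembryonic (-0.49) and WNT pathway genes (-0.32) stayed below 0. Mean coverage per listed site was 17.9 in Tdg and 8.04 in wt cells. Other members with large ratios were Gata3 (41 against 3, 1.47) above, and Sycp2 (2 against 2, -2.90), Myh7 (8 against 3, -2.35), Mov10l1 (7 against 4, -2.01) and Mirg (9 against 5, -1.71) below. Prdm14 had 22 against 3 (1.15), Krt14 10 against 1 (1.15) and Rif1 13 against 4 (-0.55); the signs of Pkm, Mov10l1, Prdm14, Krt14, Rif1 and Nectin4 depended on the positions or the coverage minimum used.

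Over the 15054 genes listed in both genotypes in serum-2i, 1832 were higher in Tdg cells and 3241 lower, or 2375 and 2554 with median-ratio scaling and 2399 and 2527 with trimmed-mean scaling; 4213 further genes were listed in Tdg cells alone and 17 in wt cells alone. In number of sites, 19017 genes had more in Tdg cells and 95 fewer. As in serum, that split follows largely from the totals and from the coverage by which genes were kept. By share of sites, 98 were called higher and 505 lower. Of 14346 windows, 2014 were higher and 1244 lower (median 0.02), or 2014 and 2015 without the coverage filter, and the highest lay in the neurodevelopmental gene Auts2 (chromosome 5 from 132400001, 58 sites against 1, 4.45). At the 54406 sites listed in both, median coverage was 17.5 in Tdg and 7.5 in wt cells, and the median of the ratios per site was 2.30-fold. Across the 2892 genes with a site in all 4 groups, the Tdg over wt ratio in serum had a Spearman's rho of 0.191 with that in serum-2i (Pearson's r 0.201), and 0.351 (0.449) across the 98 genes with at least 5 sites in each group. How the effect of Tdg differed between media was not tested.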

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

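The coverage minimums, positions near span ends, spans with 2 kb flanks, unscaled coverage, other matching and lists without shared genes were chosen after seeing the data. No paired analysis was possible because the table holds group means only and its columns carry no replicate. For the same reason count-model tests with a further tool, set tests on those models, a fit to the compared groups alone, a minimum of 2 or 3 reads per replicate, leaving out each replicate and replicate overlap were not run. Thinning reads to the shallowest library, promoters by strand, gene strand, strand symmetry and summing of strands were not run either, as the values carry neither reads nor strand. Of 84 alternatives tried on the 28 main results, 46 left the result the same; where it moved, the cause was not tested.

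With the number of sites in place of coverage, 1724 genes were higher and 2814 lower for serum-2i over serum in Tdg cells, and 98 and 505 for Tdg over wt in serum-2i. Within 1 kb of span ends, 1628 genes were higher and 5258 lower in the first comparison, which reverses its balance, and 430 were higher and 1882 lower in the second. Without the coverage filter 4938 genes and 2015 windows were lower for Tdg over wt in serum-2i. Windows of 1 Mb gave 1006 higher and 83 lower for the media in Tdg cells, and 336 and 26 for Tdg over wt in serum-2i.

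Median-ratio scaling gave 4197 windows higher and 3609 lower for the media in Tdg cells, and trimmed-mean scaling 4123 and 3700. At sites listed in both, median-ratio scaling gave 36757 higher and 37544 lower, unscaled coverage 39918 and 35500, and a mean coverage of at least 20 left 41279 lower. Scaling by total coverage turned the median log2 at shared sites to -0.67 and -3.47 for the media in Tdg and wt cells, and to -5.23 and -2.59 for Tdg over wt in serum and serum-2i.

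With coverage minimums of 6 and 10, the ratio of listed sites was 41.0 and 102 for the media in wt cells and 187 and 1185 for Tdg over wt in serum; in serum-2i it was 20.6 at a minimum of 10. Near gene ends lay 14.8% of serum wt sites at a minimum of 6. By share of coverage the figure was 11.7% in serum Tdg and 5.07% in serum-2i Tdg cells, and X over autosomes was 0.0516 in serum-2i wt, 0.0841 in serum Tdg and 0.0955 in serum-2i Tdg cells. Without the shared genes the extraembryonic list had a median of -0.10.

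Near span ends the sign turned, for the media in Tdg cells, for Grin2b (-3.60), Ctnnb1 (-2.17), Ldha (-0.90), Pkm (-0.89), Myh7 (2.44), Cd8a (-0.43) and Actn3 (1.05). For Tdg over wt in serum-2i it turned for Prdm14 (-1.35), Mov10l1 (0.10), Pkm (-0.22), Krt14 (-1.62) and Nectin4 (-0.76). With 2 kb flanks it turned for Krt14 (-0.24), and with a minimum of 6 for Rif1 (0.0273).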

Other observations

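Of the tests in this part, those of the wt groups, of the site numbers of other genes and of the Sfi1 window were chosen after the results were seen, and the others were written before they were run. Gene families not described above also differed between media in Tdg cells. Of the forkhead (Fox) genes listed in both media, 14 were lower in serum-2i and 3 higher of 29 (1550 sites in serum-2i against 1092 in serum), and of the Sox genes 7 were lower and 1 higher of 10 (417 against 267). The paired-box (Pax) genes had 6 lower and none higher of 8, with 492 sites in serum-2i against 821 in serum, and all 4 Irx genes listed in both were lower (29 against 139 sites). Clustered protocadherins (Pcdha, Pcdhb and Pcdhg), which give neurons their surface identity, had 14 lower and none higher of 35, with 2277 sites against 2498. Where spans of such clustered genes overlap, a site was counted for each of them, so the members and totals are not independent counts.

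Among receptor genes of smell, 53 of 1106 olfactory receptor (Olfr) genes and 34 of 353 vomeronasal (Vmn) genes had a listed site in any group; span length and CG density were not matched, and unlisted positions have unknown values. Ribosomal protein genes (Rpl and Rps) had a site in 28 of 77 members. Keratins (Krt) had 8 lower and 2 higher of 26 in serum-2i over serum in Tdg cells. These families were chosen after their values were seen, and their ratios were not matched on span length.

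The lower share of the bivalent lineage regulators in serum-2i was set against 3 technical explanations. Short spans with dense sites could give such a ratio, but random lists matched on span and coverage ran from -1.86 to -0.55, and the list lay outside them at -2.90 (percentile 0). A bias of the Tdg libraries alone would leave the wt groups unaffected, yet the list's summed log2 ratio there was -2.39, against -1.54 to 0.39 for random lists. Fewer reads or stricter listing in the serum-2i Tdg group could lower site numbers. The other 18128 genes had a median of 1.80 times as many sites in serum-2i (interval 1.75 to 1.83), so their site numbers did not fall with those of the list. That median follows from the 1.84-fold ratio of all listed sites, known beforehand. Read numbers were unknown, so it cannot decide whether depth or listing differed. A loss of 5caC at these genes in serum-2i remains possible, and so does an effect of local CG density, which was not tested.

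The few sites on chromosome X could come from a lower copy number under a fixed coverage minimum, if the cells carry 1 X. Thinning autosomal coverage to that level would leave 0.614 of sites (0.612 to 0.615), while X had 0.121 of the autosomal density in serum-2i Tdg cells (0.0965 to 0.151). The thinning assumed independent reads and no filter but the coverage minimum, and the rule for listing is unknown. It therefore cannot exclude an effect of copy number. Fewer or shorter genes on X do not account for it alone: in protein-coding spans matched on length X had 0.172 (0.140 to 0.208, 966 genes). The kinds of genes on X, mappability, CG density and the biology of the sex chromosomes were not tested.

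The window of Sfi1, a centrosomal gene near the start of chromosome 11, had 59 and 92 sites in serum and serum-2i wt cells and 100 and 137 in Tdg cells, and Sfi1 had more sites than any other gene in serum wt cells. Reads from repeated copies, or background shared by all libraries, might explain this: the window's mean coverage per site stood at percentile 99.3 or above in every group. The Tdg over wt ratio of its share stood at percentile 0.8 or below in either medium, but the window was picked for leading both wt groups in sites, so a low ratio follows from the choice and does not argue against 5caC that TDG removes. These cases cannot be told apart here, and the triple Tet knockout control is not analysed here.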
